A study of Homo sapiens with 4 samples.

How the data were processed

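The series holds 4 libraries of capped, polyadenylated RNA from HEK293T cells, 1 for each pool of a polysome gradient. Per the labels' protocols, cells received cycloheximide at 100 ug/mL for 10 min, lysates were spun through sucrose from 10% to 50%, capped RNA was bound to beads carrying a mutant of the cap-binding protein eIF4E after lithium chloride precipitation, and the RNA was sequenced directly on a MinION. Direct RNA sequencing involves no PCR, and each read stands for 1 RNA molecule unless alignments were counted more than once. The authors' deposited values are raw counts per gene, whole numbers with no scaling. Per the submitters' processing notes, minimap2 2.15 and featureCounts from Subread 1.6.2 were used with the hg38 build. The annotation release, the treatment of reads that align to several places and the use of strand are not given in the sources used here. Genes that share reads with a near-identical copy, a retrocopy or an overlapping gene are therefore uncertain, and this covers many ribosomal protein genes.

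The table has 19948 gene symbols, all of protein-coding genes, of which 6968 had no count. No column of per-sample values was left unused. Coordinates and coding lengths came from GENCODE release 29 on the same build, and 19670 symbols matched; 99.2% of the tested genes had a coding length. This release may not be the one the authors counted against. TOP genes such as RPS10, RPL17, RPL36A and EEF1G had at most 4 counts summed over the libraries and were not tested. Some results on single genes are not reported here.

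Everything below was computed from those counts. Genes with at least 30 counts summed over the 4 libraries were tested, which left 7527. For each of the comparisons heavy polysome against free, light polysome against free, monosome against free, and heavy against light polysome, the log2 ratio of shares was taken after adding 0.5 to each count and dividing by the library total. Since a scaling factor moves all genes of a comparison alike, values for genes and lists are given relative to the median of all tested genes. The 95% counting interval of a gene is the exact conditional binomial one (Clopper-Pearson). A gene counted as higher or lower when it was at least 2-fold apart and its interval excluded equal shares, and 20 shuffles of the reads between libraries gave the number expected from counting alone if no gene differed, which says nothing of single genes. With 1 library per pool there are no residual degrees of freedom, so neither edgeR's quasi-likelihood test nor any other replicate test could be fitted. Genes with no count in one library were given as at least N-fold apart in share, not relative to the median gene, against a floor of 3 counts in that library, which is a CPM of 8.44 in the free library and 1.92 in the heavy polysome library. Where lists were rerun with genes without a count at this floor, only those genes were raised. They then stood above genes with a count below 3, and the median of all tested genes moved with them. Depth limits the free library most: 1097 genes had 10 or more counts there, against 8250 in the heavy polysome library.

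Gene lists were fixed before the data were examined, 26 in number. Of these, 3 (noncoding snoRNA host genes, mitochondrially encoded genes and nuclear long noncoding RNAs) had no member in the table and are not analysed here. A list's value is the median of its members with an exact binomial order-statistic interval, and its percentile among 10000 random lists, each made by drawing for every member 1 of the 50 genes nearest in mean expression, or in expression and coding length. Ribosomal protein genes are more abundant than nearly all others, so the matched genes were less abundant than the members. Many members also shared their nearest genes, so their 10000 lists redrew a small set of genes. The mean gradient position of a gene weights its CPM by 0, 1, 2 and 3 from free to heavy polysome.

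Genes named in the text came from a rule fixed before the data were examined. It takes, for each comparison, the 10 highest and 10 lowest ratios among genes with at least 100 counts in the pair of libraries together; for each list, its 3 most counted members and, per comparison, its highest and lowest member under the same minimum; the 10 most counted genes of each library; and EEF1A1, EEF2, PABPC1, TPT1, RPS6, RPL3, RPL13A, RPLP0, ACTB, GAPDH, ATF4, LARP1, MALAT1, GAS5, ODC1, AMD1 and FTH1. The text leaves some of them out. Genes named for their retrocopies or near-identical counts were chosen after their values were seen.

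The alternatives tried were other minimum counts (10, 100 or none), a pseudocount of 1 or none, summed counts in place of medians, thinning to the shallowest library, scaling with edgeR 4.0.16 (TMM) or DESeq2 1.42.0 (size factors) or without the TOP genes, other denominators and other position weights. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. The procedure was tested on simulated data with 7527 genes, 50 at each known fold and 7327 unchanged. The genes given a fold all had at least 100 counts in the pair, so recovery below that count was not measured. Both libraries were drawn from the mean of their shares, so most genes had more counts in the simulated free library than in the real one. In heavy polysome against free, 10% were called at 1.5-fold, 98% at 3-fold, 100% at 6-fold and 98% at 6-fold lower, with 1.75% of unchanged genes. In light polysome against free these were 8%, 98%, 100%, 100% and 1.51%, in monosome against free 6%, 98%, 100%, 98% and 1.71%, and in heavy against light polysome 2%, 100%, 100%, 100% and 1.04%. A list of 40 genes shifted by -2 on the log2 scale was estimated at -2.01, -2.02, -1.79 and -1.92 in the same order. In monosome against free its interval (-1.88 to -1.63) missed the true shift. Of 20 unshifted lists per comparison, 1 in heavy polysome against free, 3 in light polysome against free, 2 in monosome against free and 0 in heavy against light polysome fell outside the central 95% of their matched lists. These lists were random draws from the tested genes, so they do not test the matching for the more abundant ribosomal protein genes.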

Results

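HEK293T cells, a human embryonic kidney line, were treated with cycloheximide, which holds elongating ribosomes on their mRNAs, and their lysate was separated on a sucrose gradient. The lighter end of such a gradient holds mRNA without ribosomes, and mRNAs with more ribosomes travel further. Capped, polyadenylated RNA from 4 pools of the gradient (free, monosome, light polysome and heavy polysome) was read directly as RNA on nanopores, without amplification. There was 1 library per pool. The total counts on genes were 355509 in the free library, 1329334 in the monosome library, 1499401 in the light polysome library and 1564531 in the heavy polysome library. The study concerns how the ribosome loading and the poly(A) tails of TOP mRNAs depend on mTOR and LARP1, and the gradient shows where those mRNAs lie in cells with no inhibitor named in the labels. TOP mRNAs start with a run of pyrimidines next to the cap and code for the ribosomal proteins and for several translation factors. With 1 library per pool no difference could be set against a spread between replicates, and no p-value is given. Intervals below cover 95% counting error for a gene or a share. For a gene list they are 95% intervals of its median, with members taken as independent draws. Single members can lie far outside them. All values are shares of a library, because the RNA mass of each pool is not given in the sources used here.

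Ribosomal protein mRNAs made up most of the free library and a minor part of the heavy polysome library. The 79 ribosomal protein genes took 65.4% of the counts in the free library (Clopper-Pearson interval 65.2 to 65.6), 55.0% in the monosome library (54.9 to 55.1), 31.7% in the light polysome library (31.7 to 31.8) and 19.2% in the heavy polysome library (19.1 to 19.3). All 97 TOP genes together took 67.9%, 58.5%, 33.3% and 22.5%. The 18 TOP genes that do not code for ribosomal proteins, among them the elongation factors EEF1A1 and EEF2 and the poly(A)-binding protein PABPC1, kept a small share with no such trend, with 2.47%, 3.50%, 1.52% and 3.34%. RPS2 (chromosome 16, 1962052 to 1964860), a small-subunit protein, alone took 15.1% of the free library, 6.79% of the monosome library and 2.04% of the light polysome library. The 10 most counted genes took 43.6% of the free library and 6.88% of the heavy polysome library.

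**Figure D1:**
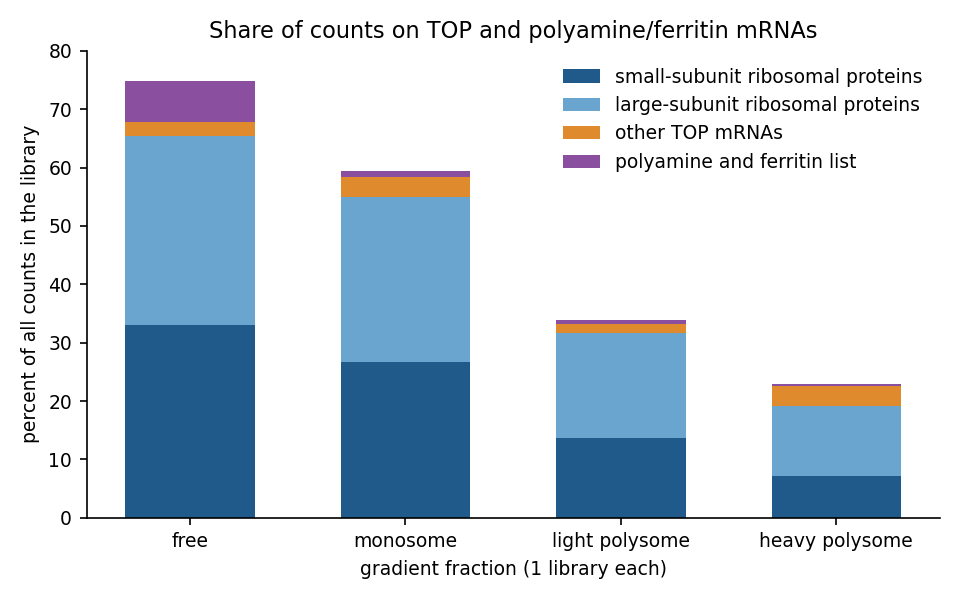
Percent of all counts in each of the 4 libraries that lie on small-subunit ribosomal protein genes, large-subunit ribosomal protein genes, other TOP genes and the polyamine and ferritin list (stacked bars, 1 library per fraction). The small-subunit part goes from 33.1% in the free library to 7.10% in the heavy polysome library, and the polyamine and ferritin part is largest in the free library.

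The heavy polysome library was compared with the free library to ask which mRNAs carry many ribosomes. Ribosomal protein mRNAs lay far toward the free end, with 74 of the 75 tested genes below the median gene and a median log2 ratio of -4.22 relative to it (interval -4.69 to -3.72). RPLP1, a protein of the ribosomal stalk, lay at -8.58 (-8.63 to -8.52), and RPS2 at -7.95 (-7.98 to -7.91). RPL3 (chromosome 22, 39312882 to 39320389), a long member of the large subunit, was the exception at 0.00 (-0.21 to 0.24). Non-ribosomal TOP mRNAs lay closer to the median gene: their median was -0.60 (-1.22 to 0.71), with 7 of 17 above the median gene, and 0.47 with genes without a count set at a floor of 3. With the monosome library in place of the free one they lay at -1.49 (-2.56 to -0.56), still above the ribosomal protein mRNAs at -3.12 (-3.51 to -2.73). Within that group TPT1 lay at -6.54 (-6.62 to -6.47), while EEF1A1 lay at -0.99 (-1.10 to -0.88), EEF2 at 0.23 (-0.20 to 0.72) and the nucleolar chaperone NPM1 at 1.25 (0.99 to 1.54).

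Both ferritin mRNAs were among the most free-bound of all. FTL (chromosome 19, 48965301 to 48966878) had 12074 counts in the free library and 453 in the heavy polysome library, which put it at -9.92 (-10.06 to -9.78). FTH1 (chromosome 11, 61959718 to 61967660) had 12416 and 1240 counts and lay at -8.51 (-8.59 to -8.42). YBX1, an abundant mRNA-binding protein, lay at -6.55 (-6.60 to -6.50). At the other end were ANAPC5, a subunit of the anaphase-promoting complex, and CCT2, a subunit of the cytosolic chaperonin. Neither had a count in the free library, and against a floor of 3 counts their shares were at least 44.4-fold and 34.0-fold higher in the heavy polysome library, where the share of the median gene was 8.26-fold higher. The initiation factor EIF4H had 1 count against 1183 and lay at 4.44 (2.54 to 10.33).

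Among the other gene groups, mRNAs of the tricarboxylic acid cycle had a relative median of 1.39 (0.57 to 2.45), with 15 of 16 above the median gene. Non-TOP initiation factors followed at 1.36 (0.24 to 1.90), hnRNP and splicing factors at 0.87 (0.37 to 1.25), proteasome subunits at 0.78 (0.40 to 1.82), nucleolar ribosome biogenesis factors at 0.63 (0.31 to 1.36) and replication and cell cycle genes at 0.54 (0.22 to 1.05). With genes without a count at the floor the last 4 lay higher, at 1.87, 1.84, 1.36 and 1.45. Oxidative phosphorylation genes lay below the median gene at -1.25 (-1.48 to -0.99), with 59 of 70 below it, but at -0.22 at the floor, and the log2 ratio of their summed counts lay at -1.40 against the median gene but 1.66 above that of all other genes summed. Mitochondrial ribosomal proteins lay at -0.88 (-1.36 to -0.22), a direction that turned to 0.17 when genes without a count were set at the floor. Only 1 of their 73 tested members lacked a count, so the others moved only through the median of all tested genes. Intervals that included 0 were found for glycolysis (1.08, -0.50 to 1.93), cytosolic chaperones (0.84, -0.24 to 1.25), stress-response genes with upstream open reading frames (0.77, -0.89 to 1.87), cholesterol and fatty acid synthesis (0.30, -0.23 to 0.97), deadenylation and poly(A) binding (0.16, -0.70 to 1.12) and aminoacyl-tRNA synthetases (0.03, -0.46 to 1.31). They were also found for actin and tubulin (-0.01, -1.72 to 0.70), endoplasmic reticulum chaperones (-0.03, -0.57 to 0.68), unstable immediate-early mRNAs (-0.44, -1.08 to 0.60), histone variants and high mobility group proteins (-0.80, -1.41 to 0.66), the polyamine and ferritin list (-0.92, -8.51 to 0.60) and the mTOR pathway with the LARP family (-1.30, -2.22 to 0.12). At the floor, cytosolic chaperones (1.90), cholesterol and fatty acid synthesis (1.13), actin and tubulin (0.95) and endoplasmic reticulum chaperones (0.86) lay above these intervals.

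The median gene itself had an 8.26-fold higher share in the heavy polysome library (log2 3.05), and 5458 of 7527 genes were at least 2-fold higher against 227 lower. Reads shuffled between these libraries gave 55 higher and 62.1 lower on average. With edgeR's TMM scaling, which lowered the log2 ratio of every gene by 2.56, the split was 931 higher and 943 lower, and with DESeq2's size factors it was 795 and 992. With the TOP genes left out of the totals it was 3008 and 488, so their share of the free library does not account for all of the excess. The TOP list as a whole lay at -3.89 (-4.43 to -3.28), at percentile 0 of 10000 random lists matched on mean expression, whose own median was -2.21, and at percentile 0 when coding length was matched too. Both kinds of list were less abundant, with a median log2 CPM of 9.69 and 9.45 against 11.64 for the TOP list. The free library had no count for 2348 of the tested genes, and with these at the floor the TOP value was -2.83 and the ribosomal protein value -3.16.

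**Figure D2:**
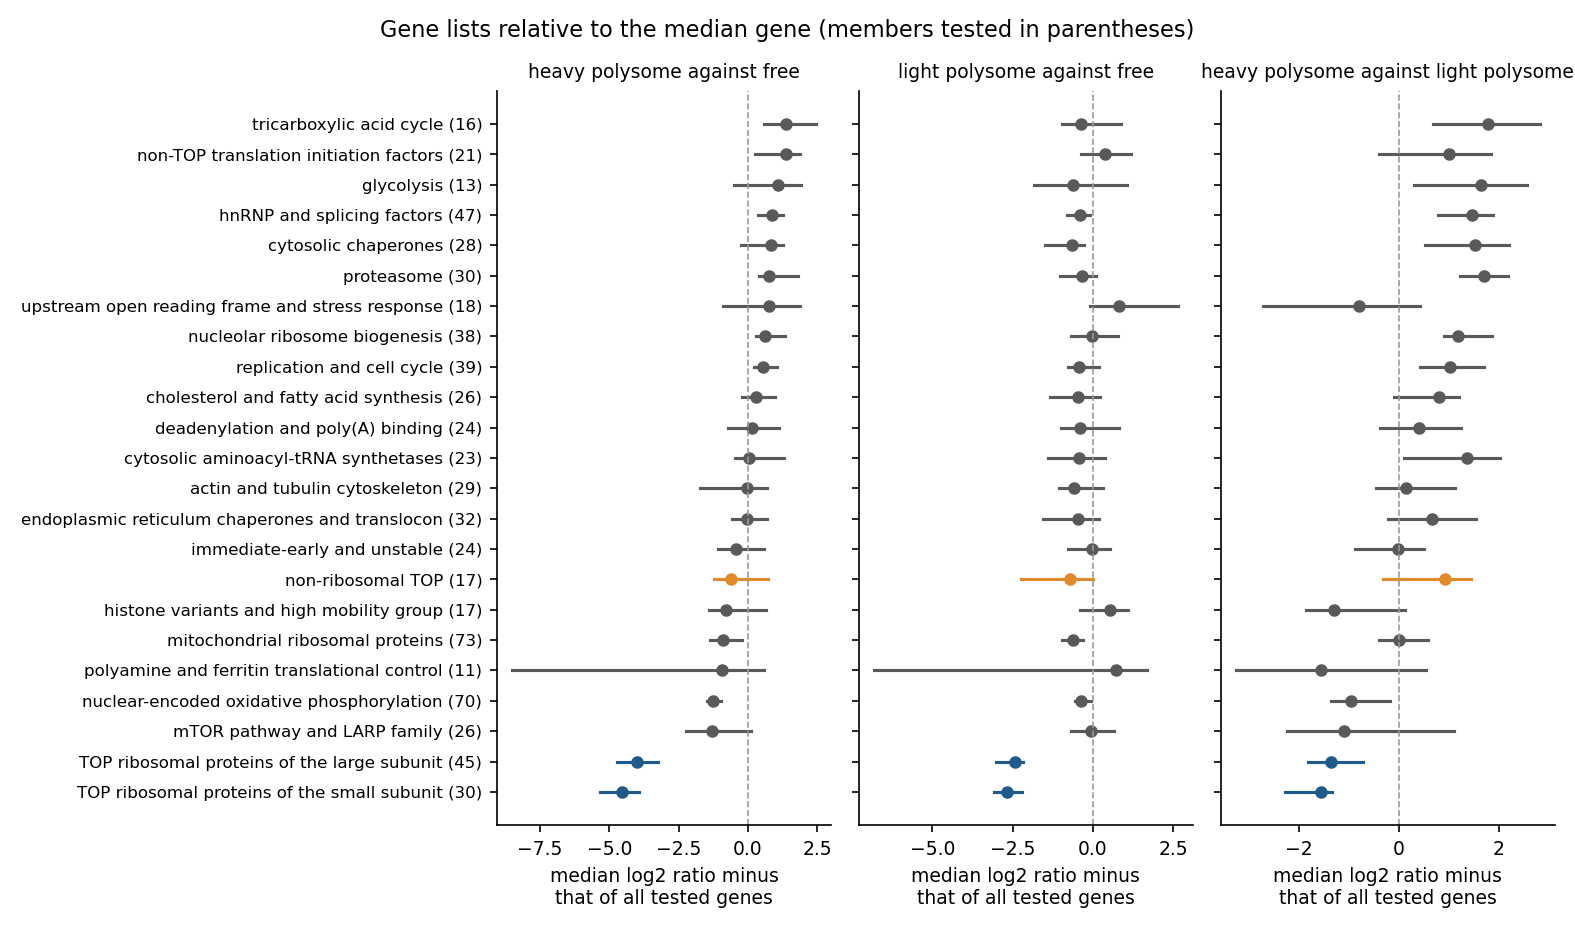
Median log2 ratio of 23 gene lists minus that of all tested genes for 3 comparisons (points), with the exact order-statistic interval over the members (lines), ribosomal protein lists in blue and non-ribosomal TOP mRNAs in orange. The small-subunit and large-subunit lists lie at -4.53 and -3.99 in heavy polysome against free, and the proteasome list is at 1.71 in heavy against light polysome.

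The light polysome library was compared with the free library to separate mRNAs with a few ribosomes from those with none. Here too the ribosomal protein mRNAs stood toward the free end, with 74 of 75 below the median gene and a relative median of -2.65 (-2.97 to -2.28). The small-subunit list lay at -2.69 (-3.08 to -2.21) and the large-subunit list at -2.42 (-3.01 to -2.16). RPL3 was again the member above the median gene, at 0.40. The genes that ranked furthest toward the light polysomes were not ribosomal: ATP6V0E2, a subunit of the vacuolar proton pump, the casein kinase CSNK1G2 and the kinases AKT1 and AKT2. They had no count in the free library, so their rank rests on the 0.5 added to each count. Their shares were at least 45.0-fold, 42.7-fold, 30.0-fold and 30.4-fold higher, against 4.82-fold for the median gene. Oxidative phosphorylation genes lay at -0.37 (-0.54 to -0.07), cytosolic chaperones at -0.65 (-1.48 to -0.29) and mitochondrial ribosomal proteins at -0.62 (-0.96 to -0.30), while the remaining non-TOP lists had intervals that included 0 apart from hnRNP and splicing factors at -0.39 (-0.81 to -0.10). These 4 directions turned with genes without a count at the floor, where the values were 0.40, 0.19, 0.23 and 0.33. That setting puts such genes above genes with a count below 3 and lowers the median of all tested genes. Only 3 of 70, 1 of 28, 1 of 73 and 3 of 47 members lacked a count, so the lowered median moved the other members. The setting therefore cannot decide these directions. Non-ribosomal TOP mRNAs lay at -0.70 (-2.25 to 0.00), and at 0.15 at the floor. No tested member of this list or of the ribosomal protein list lacked a count. At the floor their values therefore moved only through the median of all tested genes. Against the monosome library both groups were level in the light polysomes, at -1.76 (-2.51 to -1.18) for non-ribosomal TOP mRNAs and -1.61 (-1.79 to -1.42) for ribosomal protein mRNAs.

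Whether other abundant mRNAs lay as far toward the free end stayed open. The 20 non-TOP genes with a mean log2 CPM (counts scaled to a common library total) of at least 10 over this pair of libraries, chosen after the data were seen, lay at -1.31 (-3.68 to -0.33), an interval that overlapped that of the ribosomal protein genes. Their median log2 CPM was 10.71, against 11.93 for the ribosomal protein genes. In heavy polysome against free, 19 genes chosen in the same way, both ferritins among them, lay at -2.14 (-5.92 to -0.48). The TOP list lay at -2.45 (-2.80 to -2.16), at percentile 0 of the less abundant random lists under both matchings, and at -1.60 with genes without a count at the floor. In total 4285 genes were at least 2-fold higher and 66 lower, against 50 and 70.55 after shuffling. The median gene lay at log2 2.27, TMM lowered every ratio by 2.03, and the splits were 808 against 538 with TMM and 704 against 601 with DESeq2.

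The monosome library was compared with the free library to ask which mRNAs sit under a single ribosome. Ribosomal protein mRNAs lay nearest the median gene here, at -1.07 (-1.26 to -0.85), with 60 of 75 below it, and at -0.36 with genes without a count at the floor. The shortest of them lay on the other side: RPL41, whose coding sequence has 75 nucleotides, had 838 counts in the free library and 19019 in the monosome library and lay at 1.33. Several translation factors were high, with EEF2 at 1.76 (1.33 to 2.25), PABPC1 at 2.56 (1.93 to 3.36) and EIF4B, which had 3 counts in the free library, at 4.16 (2.82 to 6.66). EEF1A1 had 676 counts in the free library and 18499 in the monosome library, and PABPC4, with none in the free library, had a share at least 10.3-fold higher, against 2.41-fold for the median gene. Non-ribosomal TOP mRNAs as a list lay at 0.66 (-0.64 to 1.76), an interval that included 0, and at 1.37 at the floor. Among lists matched on expression they lay at percentile 99.83, and at 97.61 when coding length was matched too. The autophagy protease ATG4D, also without a count in the free library, had a share at least 13.9-fold higher. The actin and tubulin list lay at -0.65 (-0.96 to -0.11), with 22 of 29 members below the median gene, and at 0.01 with genes without a count at the floor. Cholesterol and fatty acid synthesis lay at -0.48 (-1.02 to -0.19), or -0.05 at the floor, and mitochondrial ribosomal proteins at -0.23 (-0.42 to -0.13), or 0.48 at the floor.

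The TOP list as a whole lay at -0.96 (-1.14 to -0.67), at percentile 0.01 of the less abundant random lists, and at -0.25 with genes without a count at the floor. There were 2048 genes at least 2-fold higher and 60 lower, and shuffled reads gave 39.35 and 74.65. The median gene lay at log2 1.27, TMM lowered every ratio by 1.04, and the splits were 551 against 248 with TMM and 455 against 310 with DESeq2.

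Heavy and light polysomes were compared to ask which mRNAs carried many rather than few ribosomes. Proteasome subunits lay toward the heavy end, with 27 of 30 above the median gene and a relative median of 1.71 (1.22 to 2.18), the ATPase subunit PSMC2 reaching 3.50 (2.84 to 4.34). All 13 tested glycolytic genes lay above the median gene (median 1.65, 0.30 to 2.57), among them PGK1 at 3.44 (2.98 to 3.99), ENO1 at 2.47 (2.35 to 2.60) and GAPDH at 2.19 (2.10 to 2.27). In heavy polysome against free, GAPDH lay below the median gene at -1.68 and ENO1 above it at 1.38. The RNA-binding protein HNRNPA2B1 reached 3.97 (3.75 to 4.20), and actin ACTB with 11187 counts in the heavy and 1245 in the light library lay at 2.52 (2.43 to 2.60). The cohesin subunit RAD21 lay at 4.74 (3.52 to 6.79). At the light end were LSM10, a subunit of the particle that processes histone mRNA, at -4.45 (-5.03 to -3.96), RPL41 at -4.28 (-4.42 to -4.14), the copper chaperone COX17 at -4.12 (-4.45 to -3.82) and the stress-response transcription factor ATF4 at -3.52 (-3.64 to -3.40).

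Other lists toward the heavy end were the tricarboxylic acid cycle at 1.79 (0.68 to 2.82), cytosolic chaperones at 1.52 (0.53 to 2.20), hnRNP and splicing factors at 1.47 (0.80 to 1.88), aminoacyl-tRNA synthetases at 1.38 (0.11 to 2.02), nucleolar ribosome biogenesis factors at 1.20 (0.91 to 1.86) and replication and cell cycle genes at 1.02 (0.43 to 1.71). Ribosomal protein mRNAs lay at -1.44 (-1.70 to -1.13), with 67 of 75 below the median gene, and oxidative phosphorylation genes at -0.96 (-1.35 to -0.16). Lists matched to the latter on expression and coding length lay lower, with a median of -1.71 (percentile 99.96 for the list), as they did in heavy polysome against free, with -1.86 (percentile 98.74). Non-ribosomal TOP mRNAs lay at 0.92 (-0.32 to 1.45), with NPM1 highest at 3.18 (3.07 to 3.30) and the ribosome-associated scaffold RACK1 at 1.13 (1.07 to 1.20). This list lay at percentile 99.96 of lists matched on expression, and at 96.42 when coding length was matched too.

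**Figure D3:**
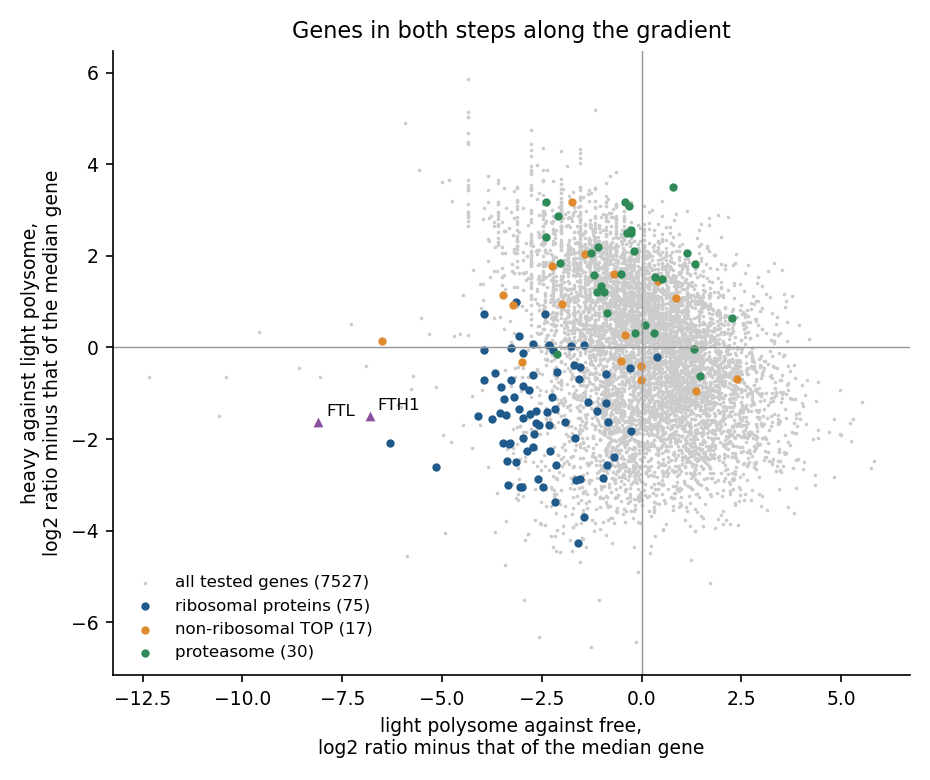
Each tested gene by its log2 ratio in light polysome against free (horizontal) and in heavy against light polysome (vertical), both relative to the median gene, with ribosomal proteins, non-ribosomal TOP mRNAs, proteasome subunits and both ferritins marked. Of the ribosomal proteins 74 of 75 lie left of 0 (median -2.65), and 27 of 30 proteasome subunits lie above 0 (median 1.71). Stripes are genes with few counts.

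Between heavy and light polysomes the ribosomal protein mRNAs lay within the range of short mRNAs. Their median was at percentile 21.9 of lists matched on expression and at percentile 61.7 of lists matched on expression and coding length, although the latter were less abundant, with a median log2 CPM of 9.56 against 11.91. The 48 non-TOP genes with a mean log2 CPM of at least 10 over both libraries, of longer coding sequence, lay at -0.47 (-1.32 to 0.14). Across 7392 other genes the heavy to light ratio went with coding length, with a Spearman rho of 0.308 across genes, which are not independent replicates. The 740 shortest genes, with 72 to 507 nucleotides of coding sequence, had a relative median of -1.91, 739 genes of 1230 to 1434 nucleotides had 0.73, and the 740 longest, of 2769 to 16938 nucleotides, had 0.00, so the ratio was highest at middle lengths. Light polysome against free showed no such relation, with a rho of -0.00859. The TOP list lay at -1.16 (-1.47 to -0.71), inside the range of its matched lists. Its percentile was 86.6 with expression matched and 94.9 with coding length matched too. In total 2958 genes were at least 2-fold higher and 1349 lower, against 33.95 and 31 after shuffling. The median gene lay at log2 0.59, TMM lowered every ratio by 0.53, and the splits were 2050 against 2036 with TMM and 2024 against 2058 with DESeq2.

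**Figure D4:**
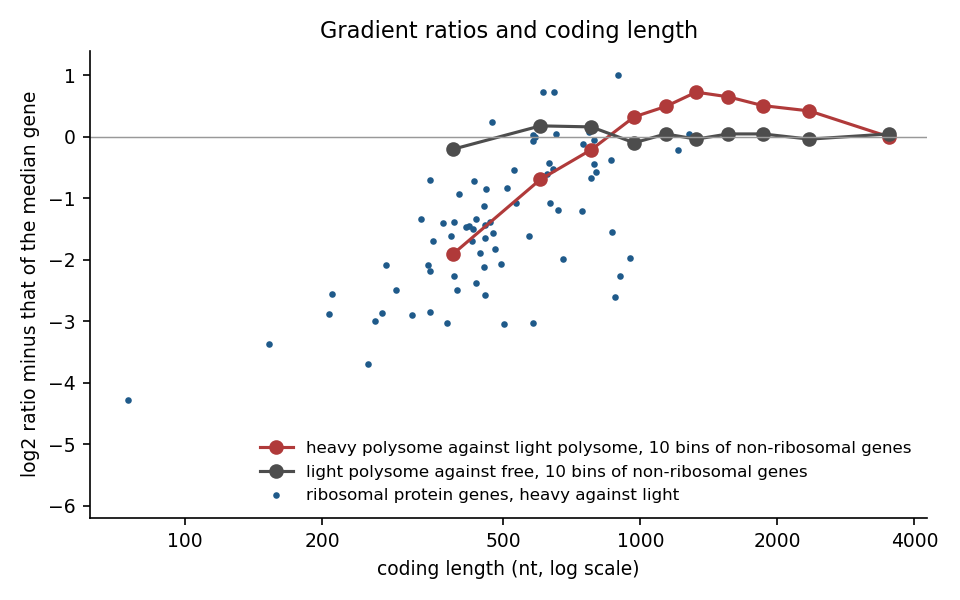
Log2 ratio relative to the median gene against coding length in nucleotides (log axis), as medians of 10 bins of non-ribosomal genes for heavy against light polysome (red) and light polysome against free (grey), with single ribosomal protein genes for heavy against light polysome (blue). The red line goes from -1.91 in the shortest bin to 0.73 in the sixth bin and back to 0.00 in the longest, and the grey line stays between -0.20 and 0.18.

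Taking the 4 libraries at equal weight, the mean position along the gradient, from 0 for free to 3 for heavy polysome, had a median of 2.25 over all tested genes, 1.18 (1.11 to 1.33) over ribosomal protein genes and 1.90 (1.62 to 2.12) over non-ribosomal TOP genes. The TOP list as a whole lay at 1.30 (1.18 to 1.39). Single genes had distinct profiles. FTL had 91.9% of its summed CPM in the free library, RPL41 had 69.0% in the monosome library, ATF4 had 44.9% in the light polysome library, and NPM1 had 82.8% in the heavy polysome library.

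**Figure D5:**
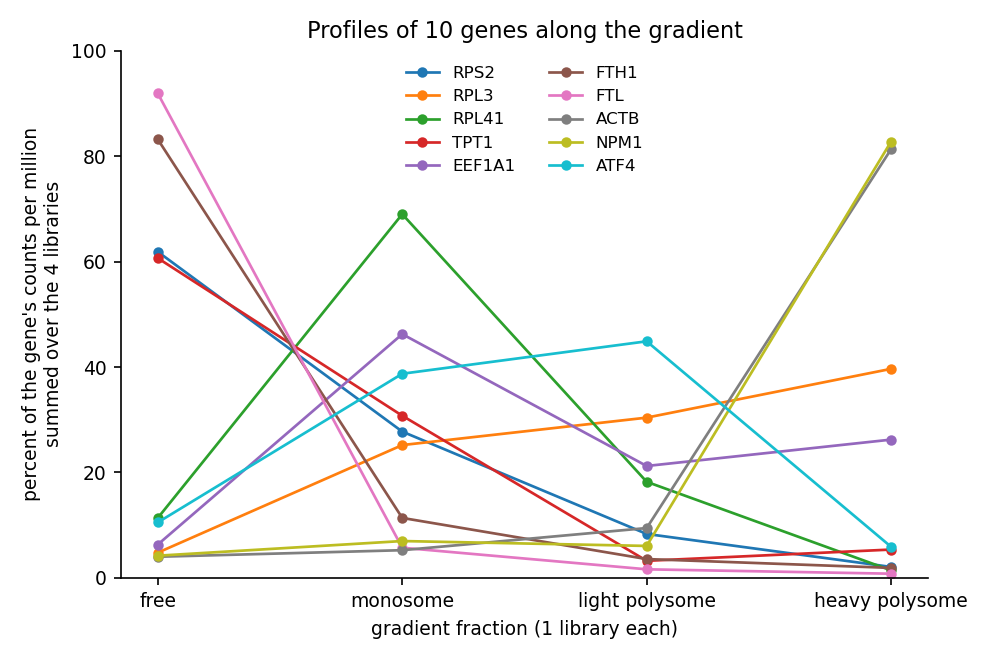
For 10 named genes, the percent of the scaled counts summed over the 4 libraries that lies in each library (points joined by lines, 1 library per fraction). FTL and FTH1 peak in the free library at 91.9% and 83.2%, RPL41 in the monosome library at 69.0%, and ACTB and NPM1 in the heavy polysome library at 81.3% and 82.8%.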

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

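Tests that set genes without a count at the floor, took the monosome library as the reference, left out genes overlapping retrocopies, used the median gene as the zero for counts of genes or for summed counts, or compared abundant non-TOP genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each pool has 1 library. The TOP and ribosomal protein medians stayed below 0 in all 4 comparisons under every alternative run, and thinning to the shallowest library, a minimum of 100 and leaving out retrocopy overlaps kept them within their intervals. Their size depended on how low free-library counts were treated and on the reference. Except at the floor, the cause was not tested. In heavy polysome against free, the TOP median was -2.84 with no minimum, -2.86 from summed counts, -2.83 at the floor and -2.84 with the monosome reference, and the ribosomal protein median was -3.30, -2.99, -3.16 and -3.12, and -3.68 with a pseudocount of 1. In light polysome against free, the TOP median was -2.07 at a minimum of 10, -1.64 with no minimum, -2.01 with a pseudocount of 1, -2.08 from summed counts, -1.60 at the floor and -1.62 with the monosome reference; the ribosomal protein median was -2.27, -1.80, -2.21, -2.02, -1.80 and -1.61. In monosome against free, the TOP median was -0.27 with no minimum, -0.60 with a pseudocount of 1, -0.59 from summed counts and -0.25 at the floor, and the ribosomal protein median was -0.38, -0.71, -0.63 and -0.36, and -0.84 at a minimum of 10. In heavy against light polysome the ribosomal protein value from summed counts was -0.97. Summed counts take all other genes as their zero; against the median gene they were -4.64 for TOP and -4.81 for ribosomal protein genes in heavy polysome against free. Among lists whose interval excluded 0, directions turned for the non-ribosomal TOP list in light polysome against free (0.18 with no minimum, 0.15 at the floor), for mitochondrial ribosomal proteins in heavy polysome against free (0.25 with no minimum, 1.53 from summed counts, 0.17 at the floor) and for oxidative phosphorylation there (1.66 from summed counts). Both summed values turned through the change of zero (-1.53 and -1.40 against the median gene). Also turned at the floor, with values given above, were oxidative phosphorylation, cytosolic chaperones, mitochondrial ribosomal proteins and hnRNP genes in light polysome against free, and mitochondrial ribosomal proteins and actin and tubulin in monosome against free. Turns with no minimum had no cause tested. With the monosome reference the non-ribosomal TOP list lay at -1.49 in heavy and -1.76 in light polysome. Over the 20 other lists in heavy polysome against free, 153 of 200 values stayed within the interval, 43 moved outside it and 4 turned from an interval that excluded 0. Counting lists whose interval included 0, 29 values over 11 lists changed sign, among them mTOR and LARP, histone variants, immediate-early mRNAs and the polyamine and ferritin list. The non-ribosomal TOP list there also changed sign (0.53 with no minimum, 0.45 from summed counts, 0.47 at the floor). These directions are not settled. Counts of genes at least 2-fold apart depended on the scaling. In heavy polysome against free, 5685 genes became 1874 with TMM, 1787 with DESeq2, 3496 without the TOP genes in the total, 3705 at a minimum of 100 (fewer genes tested) and 1631 relative to the median gene. In light polysome against free, 4351 became 1346, 1305, 2370 without the TOP genes and 1254 relative to the median gene; in monosome against free, 2108 became 799, 765 and 730 relative to the median gene. In heavy against light polysome, 4307 became 2614 at a minimum of 100. Leaving the 20 most counted non-TOP genes out of the denominator put the TOP share at 81.4%, 62.7%, 35.4% and 24.0% from free to heavy polysome; the planned denominator without mitochondrially encoded genes was not run, as the table has none. The mean TOP position was 2.00 with weights up to 6 (all genes 4.00), 0.72 with TMM (1.76) and 0.69 with DESeq2 (1.73). A set of 43 abundant non-TOP genes chosen on the monosome and light polysome libraries lay at -3.15 in heavy polysome against free, -0.24 in light polysome against free and -2.40 in heavy against light polysome, but that choice biases the ratio, so it decides nothing. Scaling cannot move a gene's value relative to the median gene, so its run on named genes tests nothing. Depth limits the free library (2348 tested genes at 0).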

Other observations

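The tests of the abundant non-TOP genes, of light polysome against free, of the monosome reference and of non-ribosomal TOP mRNAs and of coding length classes, and the search for near-identical counts, were chosen only after the result was seen. For the matched lists in both heavy polysome comparisons, the ferritins and the retrocopies, the pattern had been seen but the outcome counting for or against was written down before the test was run. Among the ribosomal protein mRNAs themselves, coding length went with the heavy to light ratio and not with the light to free ratio, with Spearman rhos of 0.617 and 0.0421 across 75 genes. The 23 genes with under 400 coding nucleotides lay at -2.49 (-2.88 to -1.70) in heavy against light polysome and the 24 with 600 or more at -0.49 (-1.19 to -0.05), while in light polysome against free they lay at -2.32 (-2.82 to -1.63) and -2.37 (-2.97 to -1.54). The 28 genes between these lengths lay at -1.46 (-1.69 to -1.07) in heavy against light polysome and lower than both others, at -3.03 (-3.39 to -2.63), in light polysome against free. RPL5, a long member, lay at 1.00 in heavy against light polysome, and RPS27, a short one, at -3.70.

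Genes of polyamine synthesis and its control were spread over the gradient. AMD1, which makes decarboxylated S-adenosylmethionine, lay at 0.54 (0.20 to 0.90) in heavy against light polysome, ODC1, the ornithine decarboxylase, at -1.55 (-1.67 to -1.44), and the antizyme OAZ1, made through a frameshift, at -3.26 (-3.50 to -3.03). LARP1, a protein that binds TOP mRNAs, lay at 0.76 (0.35 to 1.20). Among cell cycle genes the replication clamp PCNA lay at 2.41 (2.14 to 2.70), and among chromatin proteins HMGN2 lay at -3.01 (-3.07 to -2.94).

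Ribosomal protein mRNAs were low in heavy polysome against free, and part of this may follow from short coding sequences and abundance. Lists matched on expression and coding length did not reach it (percentile 0) but were less abundant than the members, and high abundance stays open: non-TOP genes with a mean log2 CPM of at least 9, 10 and 11 lay at -1.42 (-2.41 to -0.39, 51 genes), -2.14 (-5.92 to -0.48, 19 genes) and -5.55 (-9.92 to -1.68, 6 genes). The last interval spans all 6 genes, from FTL to GAPDH. Both ferritin mRNAs are in each of these nested sets, so the fall with abundance leans on them in part. A shallow free library as the whole cause is argued against by -3.12 (-3.51 to -2.73) with the monosome library as the reference. The non-ribosomal TOP mRNAs lay at -0.60 (-1.22 to 0.71), wholly above the ribosomal protein interval and within the range of their length-matched lists (percentile 38.2, median -0.43). Their coding sequences are longer (median 1335 nucleotides against 468) and they are less abundant (median log2 CPM 8.08 against 11.91). The contrast therefore cannot tell TOP status from length or abundance. Their summed counts lay at -2.61 against the median gene, and their median at -1.49 with the monosome reference. In light polysome against monosome both groups were level, at -1.76 and -1.61. A property of all TOP mRNAs stays open. Between heavy and light polysomes, short coding sequences could account for the value, which lay at percentile 61.7 of the matched lists. Lists matched on expression alone also reached it (percentile 21.9), so the matched lists cannot tell length from abundance.

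In light polysome against free, short coding sequences are argued against by the matched lists, which did not reach the -2.65 of the ribosomal protein mRNAs (percentile 0), and coding length did not go with this ratio. High abundance stays open: the 20 abundant non-TOP genes lay at -1.31 (-3.68 to -0.33). With a lower minimum of 9 on the log2 scale, 68 less abundant genes lay at -0.36 (-0.71 to -0.15), and with 11, 8 genes lay at -3.73 (-8.10 to 0.54). The last interval spans all 8 genes. A candidate explanation is a pool of ribosomal protein mRNAs held without ribosomes. It remains a hypothesis, untested here, since no sample with altered mTOR or LARP1 is analysed here and reads shared with pseudogenes were not excluded.

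Both ferritin mRNAs lay nearer the free end than other mRNAs of like coding length. Of 443 non-ribosomal genes within 20% of the coding length of FTH1 and with at least 100 counts, 1 was lower, FTL itself (percentile 0.226). Of 419 genes for FTL none was lower, and FTH1 came next. Both had already been seen among the lowest of all genes, so their low rank here was foreseeable. The genes compared had medians of -0.70 for FTH1 and -0.88 for FTL, so short coding sequences alone do not account for such values. The genes compared were not matched on abundance, which stays open. Ferritin mRNAs carry an iron-responsive element that blocks initiation when iron is scarce, and such a block may be at work, but iron supply is not in the labels and that explanation was not tested. Reads shared with the many ferritin pseudogenes also stay open.

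Several genes that overlap a retrocopy may owe counts to its parent gene. AC010422.3 with 35227 counts overlaps the RPL10 copy RPL10P16, and COMMD1 with 33868 counts overlaps the RPSA copy RPSAP26. Over 22 such genes the median distance to the parent gene in heavy polysome against free was 1.41 log2 units, against 2.93 (1.88 to 3.93) for shuffled pairs (percentile 0.17), consistent with reads of the parent counted on the overlapping gene. Only 8 of the 22 lay within 1 log2 unit of the parent and 6 lay more than 3 away (ANKRD16, TBCE, DNAJC10, PKN2, LRRC23 and VPS53). TTC19 is 1 of the 8 by this distance, at -9.44 against -8.58 for RPLP1. Its profile did not follow RPLP1, with 2054 counts in the free and 100 in the monosome library against 31331 and 22540. A distance in 1 comparison can thus count unlike profiles as alike. No biological explanation was tested.

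Of 642 genes with at least 1000 counts, 12 pairs had counts within 5% of each other in all 4 libraries. They include 10 pairs among the near-identical genes CBWD1, CBWD2, CBWD3, CBWD5 and CBWD6, with 44 to 46 counts in the free library and 641 to 649 in the monosome library, and the pair U2AF1 and U2AF1L5, with 1532 and 1533 counts in the heavy polysome library. The remaining pair, SNRPG and UQCR10, are unrelated genes.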
